A study of Mus musculus with 12 samples.

How the data were processed

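Left ventricles of 12 male C57BL/6 mice were measured, each on its own Affymetrix whole-genome mouse array, an oligonucleotide array that reads each transcript through 1 or more probe sets. The labels put 3 mice in each of 4 groups: transgenic (TG) or non-transgenic (NTG) littermates, each given tamoxifen or vehicle. Per the labels, every replicate was a separate heart on its own array, and nothing in the labels says that a replicate number links mice across groups. The labels conflicted for a pair of arrays. The title of TG vehicle 3 says vehicle while its treatment field says tamoxifen, and TG tamoxifen 1 is given an age of 40 weeks where the others are given about 30 weeks. Groups were taken from the titles.

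The values the authors deposited are intensities on a linear scale, 1 per probe set and array, from 1.02 to 537040. The mean after trimming 2% at each end was 2500.02 on every array, so the deposited intensities had been scaled by 1 factor per array to a common target. The labels point to the Affymetrix expression protocol, and further details of the scanning and summarisation software are not given in the sources used here. No detection calls were used here. The number of arrays limits the precision of every comparison.

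Intensities were taken as log2(value + 16). The rule for scaling, set before the data were examined, was to keep the deposited scaling if the medians of the arrays lay within 0.2 log2 of each other. They spanned 0.356, so quantile normalization was applied. Fold changes are on this offset scale, which understates changes of dim genes. Of 45101 probe sets, 64 were control probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Genes were named only from probe sets with 1 symbol. Updating symbols through the gene identifiers changed 0 of them, and 204 of these probe sets had no entry in the RefSeq table and kept the platform's symbol. Of a gene's probe sets, the one with the highest mean over the 12 arrays stood for it. The 18193 genes with a probe set were reduced to 11166 by leaving out those whose probe set lay below the 50th percentile of all probe sets, an intensity of about 670.3. Probe sets that the platform marks as possibly matching several transcripts stood for Ttll1, Tmem25, Selenos, Acaa2, Atp5d, Dlat, Ldhb, Tpi1, Socs3, Mcm5, Aif1, Acadsb, Tmx3, Ets1, Hbb-b2, Dnajb5, Notch3, Vldlr, Exoc3l2 and Mcm3, so their values may include related transcripts. Other probe sets of the same gene passed the threshold in the opposite direction for Yy1 in TG tamoxifen against TG vehicle and for Dnajb5 in TG vehicle against NTG vehicle.

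Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in 1 fit of 4 group means over all 12 arrays, with 8 residual degrees of freedom and 3.55 prior degrees of freedom. The p-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison, with a threshold of 0.05. An adjusted p given for a gene is from this fit unless the text names another fit, arrays left out or all probe sets tested. The ± beside a log2 change is its standard error (SE), and n is 3 arrays per group. Intervals are at 95%. The comparisons were TG tamoxifen against TG vehicle, NTG tamoxifen against NTG vehicle, TG vehicle against NTG vehicle, TG tamoxifen against NTG tamoxifen, the difference between the tamoxifen effects in TG and NTG, and TG tamoxifen against the mean of the other 3 groups. Lists of genes (36 lists with 853 entries, of which 34 had at least 3 tested genes) were written before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists in a comparison. With the correlation between genes estimated from the data, 0 of 34 lists passed the threshold in any of the comparisons when all arrays were used. Without the array labelled NTG tamoxifen 1, 7 lists passed that test in TG tamoxifen against TG vehicle: ER chaperones and folding (adjusted p = 0.0226), sensors and transcription factors of the unfolded protein response (0.0407), and ER-associated degradation, translocation and glycosylation, ATF4 targets, fatty acid oxidation and cell cycle (0.0332 each). The ER chaperone list also passed in TG tamoxifen against the mean of the other 3 groups (adjusted p = 0.0332).

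Genes were named by a rule set before the data were examined. Rcan1 (the gene called MCIP1 in the series title), Atf6, Esr1 and Hspa5 were always named. In TG tamoxifen against TG vehicle the 10 largest rises and 10 largest falls with no overlap between the arrays of the groups were named, with up to 4 genes of each list by smallest adjusted p. The other comparisons took the 5 largest in each direction and up to 2 genes per list. Predicted genes were passed over. The text gives list genes only for lists past the camera threshold, with a few further lists in the main comparison, a narrowing that was chosen after the values had been seen. Erlec1, Srp68, Ddit4, Vldlr and Dusp1, the genes of small counts, and the atrial genes Myl7, Myl4 and Sln were named outside the rule, after their values had been seen.

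The fit was tested on simulated data with 200 genes changed in TG tamoxifen among 11166. For TG tamoxifen against TG vehicle the first draw recovered 39% of genes changed by 1 log2 unit, with 9.30% false calls, and 90.5% of those changed by 2, with 7.18% false calls. These values vary with the draw: over 20 further draws it recovered 30.5% to 47% at 1 log2 unit, with 0% to 10.4% false calls (mean 5.68%), and 86% to 94.5% at 2, with 3.23% to 6.81% (mean 5.12%). For the difference between the tamoxifen effects the first draw recovered 0% at 1 log2 unit and 74% at 2. The further draws recovered 0% to 5% at 1. Only 4 of them made any call there, with 0% to 100% false calls (mean 27.5%). At 2 the further draws recovered 69% to 80.5%, with 1.23% to 7.98% false calls. The first draw made 0 calls in the 2 comparisons with no simulated change, and camera gave 7 of 200 random lists a p under the threshold. The simulated genes varied independently of each other. These false-call rates therefore do not cover genes that vary together, as the members of a real list may. The Benjamini-Hochberg adjustment also depends on how many genes change. In the data 2774 genes passed in TG tamoxifen against TG vehicle and 1593 for the difference between effects, against 200 changed in the simulation. The recovered shares therefore do not carry over to these data. No array was a copy of another: at least 99.9956% of probe sets differed between any pair of arrays.

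The alternatives were offsets of 1 and 64, the deposited scaling without quantile normalization, median centring, no filter and a filter at the 75th percentile, the mean of a gene's probe sets or the one with the largest SD, eBayes with trend and robust, array weights, a replicate block, only the arrays of the groups compared, TG vehicle 3 grouped as TG tamoxifen, and leaving out each array in turn. Fits without the array labelled NTG tamoxifen 1 in comparisons that do not use it, without both arrays with conflicting labels, and with an estimated correlation in camera while an array was left out, were added after seeing the data. Coordinates are not given, since no genome build was used.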

Results

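The series asked which genes of the mouse heart respond to ATF6, a transcription factor of the endoplasmic reticulum (ER) stress response. The TG mice carry ATF6-MER, a fusion of ATF6 to a mutated mouse estrogen receptor domain that responds to tamoxifen, so the drug can switch the fusion on. Expression in the left ventricle was measured on 12 arrays, 3 per group: TG tamoxifen, TG vehicle, NTG tamoxifen and NTG vehicle. The median intensity per array ran from 648 to 834. Spearman's rho between pairs of arrays lay between 0.836 and 0.916. The first principal component held 42.4% of the variance and placed TG tamoxifen arrays at -61.6 to -57.2, and all other arrays at -1.06 or above. The ratio of 3' to 5' signal of the beta-actin control, a sign of RNA degradation, was 1.81 ± 0.0671 (SD, n = 3) in TG tamoxifen, 1.5 ± 0.177 in TG vehicle, 1.89 ± 0.0987 in NTG tamoxifen and 2.28 ± 0.158 in NTG vehicle. Each other group differed from NTG vehicle with p = 0.1 in an exact two-sided permutation test, the smallest p that 3 against 3 arrays allow.

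**Figure D1:**
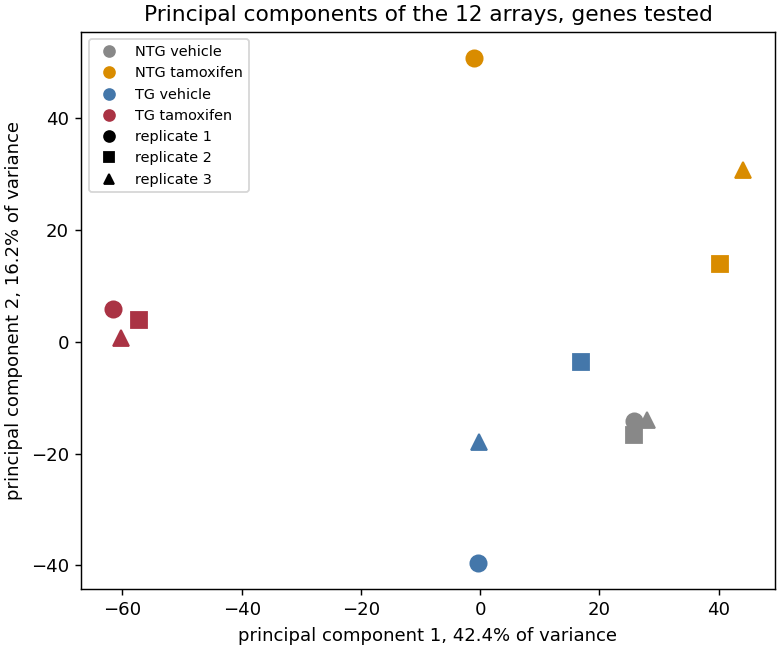
First and second principal components of the log2 expression of the tested genes, 1 point per array, with colour for the group and shape for the replicate number. The TG tamoxifen arrays lie between -61.6 and -57.2 on the first component, which holds 42.4% of the variance. On that component the array labelled NTG tamoxifen 1 lies at -1.06. The others of its group lie at 40.2 and 44.1, and TG vehicle 1 and 3 at -0.32 and -0.22. On the second component, with 16.2% of the variance, it lies at 50.9, far from TG vehicle 1 and 3 at -39.6 and -18.0. The others of its group lie there at 14.0 and 30.7.

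The transgene could be followed through Esr1, the estrogen receptor gene whose domain is part of the fusion. In TG vehicle against NTG vehicle Esr1 was higher by 10.32 ± 1.49 log2 units (adjusted p = 0.0117). The NTG vehicle arrays read 7.15 to 8.70. The other 2 Esr1 probe sets were below the filter level and did not separate the genotypes, at 5.72 to 8.70 on TG and 6.14 to 9.44 on NTG arrays, and at 8.23 to 10.04 and 9.19 to 9.88. Over 21 alternatives the difference ran from 3.43, with the mean of the probe sets, to 10.82. The adjusted p ran from 8.92e-07 to 0.101 and missed the threshold in 7 of them, among these without TG vehicle 3 (0.0544), NTG vehicle 2 (0.0749) or NTG vehicle 3 (0.0569). The 6 TG arrays read between 16.66 and 18.25 log2 units. Among the NTG arrays, the array labelled NTG tamoxifen 1 read 17.72, within the TG range, and the others read 10.88 or less. Its level thus goes against its NTG label, and every comparison that uses NTG tamoxifen rests on a group that holds it. Hspa5, the ER chaperone also called BiP, read 18.05 on the same array, against 15.65 and 15.49 on the other NTG tamoxifen arrays.

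**Figure D2:**
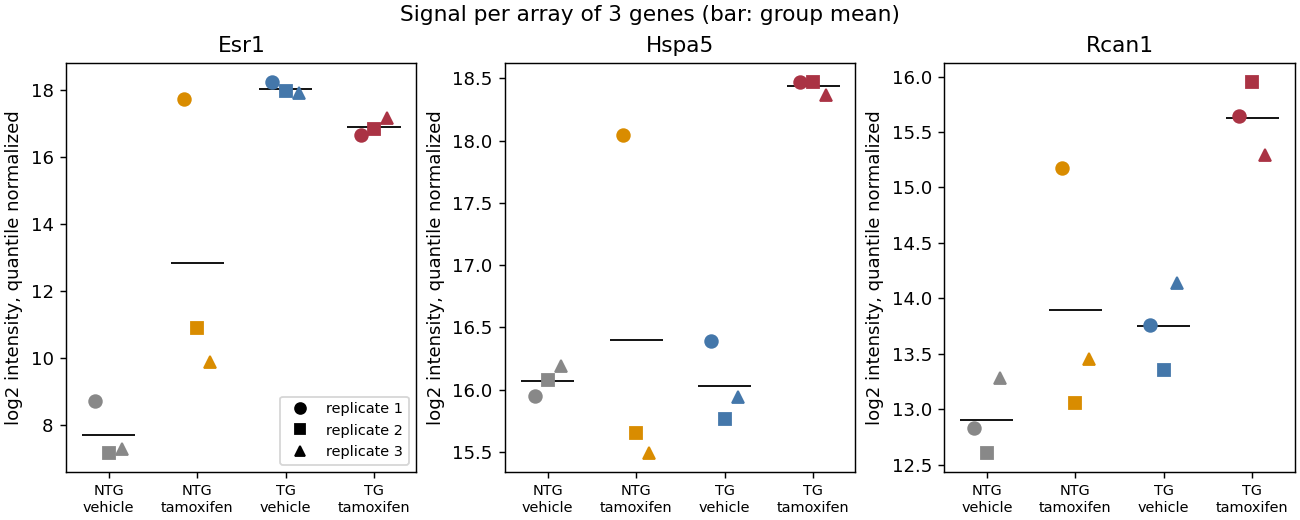
Log2 intensity after quantile normalization of Esr1, Hspa5 and Rcan1, 1 point per array in each of the 4 groups, with bars at the group means. The array labelled NTG tamoxifen 1 (orange circle) reads 17.72 for Esr1, 18.05 for Hspa5 and 15.17 for Rcan1, above the other NTG arrays for each gene; the TG tamoxifen arrays read 16.66 to 17.15, 18.37 to 18.47 and 15.29 to 15.95.

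TG tamoxifen against TG vehicle compared the fusion with and without the drug. Of 35 tested ER chaperone and folding genes 22 rose, and of 32 fatty acid oxidation genes 22 fell; adjusted over the list alone 26 rose and 1 fell, and 26 fell. With an estimated correlation camera gave each of these lists an adjusted p = 0.330, or 0.0226 and 0.0332 without the array labelled NTG tamoxifen 1, which this comparison uses only for the spread. Hspa5 rose by 2.41 ± 0.52 log2 units (5.32-fold, adjusted p = 0.00837). Its other probe sets, both marked as possibly matching several transcripts, read 2.20 and 0.63 (adjusted p = 0.0138 and 0.0724 over all probe sets tested). Over 21 alternatives the Hspa5 change ran from 1.74 to 2.59 and its adjusted p from 1.82e-05 to 0.239. It missed the threshold with TG vehicle 3 grouped as TG tamoxifen (1.74, 0.239) and without both arrays with conflicting labels (2.35, 0.0697). Rcan1, a regulator of the phosphatase calcineurin, rose by 1.88 ± 0.45 (3.69-fold, 95% interval 0.89 to 2.88, adjusted p = 0.0133), and its other probe set gave 2.15 ± 0.58 (adjusted p = 0.0266 over all probe sets tested). Atf6 fell by 1.05 ± 0.21 (adjusted p = 0.00587); its other probe sets read -0.24 and -0.25 and did not pass, and the mean of its probe sets gave -0.52 (adjusted p = 0.0624, within 0.000556 to 0.238 over its alternatives). Esr1 read -1.14 ± 1.49 (adjusted p = 0.610), with every TG tamoxifen array (16.66 to 17.15) below every TG vehicle array (17.89 to 18.25). Over 21 alternatives its adjusted p ran from 0.00935, in the fit on only these 6 arrays, to 0.759, and it was 0.0506 without the array labelled NTG tamoxifen 1. The 3' to 5' beta-actin ratio also differed between the groups without overlap (1.75 to 1.88 in TG tamoxifen, 1.32 to 1.68 in TG vehicle, exact two-sided permutation p = 0.1), and it was not a term of the fit. Of 11166 genes tested, 2774 changed, 1166 higher and 1608 lower, and 593 of the higher and 750 of the lower changed more than 2-fold. The arrays of the groups did not overlap for 44.2% of all genes, where chance gives 10%. With median centring the split was 1542 higher and 1167 lower of 2709. Median centring moved the median log2 change of all genes from -0.07 to 0.03 here, from -0.01 to -0.16 in NTG tamoxifen against NTG vehicle, from 0.01 to -0.11 in TG vehicle against NTG vehicle, from -0.06 to 0.06 in TG tamoxifen against NTG tamoxifen, and from -0.07 to 0.18 for the difference between tamoxifen effects. Leaving out single arrays gave 1462 genes without TG tamoxifen 1, 1745 without TG tamoxifen 2, 1849 without TG tamoxifen 3 and 1700 without TG vehicle 2. With TG vehicle 3 grouped as TG tamoxifen, as its treatment field has it, limma called 0 genes, with 2280 at an unadjusted p under 0.05, and Rcan1 gave an adjusted p of 0.176, within a range of 0.000698 to 0.176 over its alternatives. Rcan1 also missed the threshold without TG vehicle 2 (1.68, adjusted p = 0.0519). TG vehicle 3 itself lay at -0.22 on the first principal component, with TG vehicle 1 and 2 at -0.32 and 16.9 and TG tamoxifen at -61.6 to -57.2. Its Hspa5 read 15.94, against 16.39 and 15.76 on those arrays and 18.37 to 18.47 in TG tamoxifen. Its Rcan1 of 14.14 lay between theirs (13.76 and 13.35) and TG tamoxifen (15.29 to 15.95). On the first 2 readings it lay with the group of its title.

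Among the largest rises were Far1, which makes fatty alcohols, by 5.41 ± 0.83 log2 units, and Ptx3, a secreted pattern recognition protein, by 5.32 ± 0.63. Ube2c, a ubiquitin carrier of mitosis, rose by 5.31 ± 1.22, Polr3k, a subunit of RNA polymerase III, by 4.88 ± 1.03, and Tk1, a thymidine kinase of dividing cells, by 4.19 ± 1.12. Mthfd2 (4.34 ± 0.56) and Psat1 (4.02 ± 0.81), enzymes of folate and serine metabolism, and the chemokine Ccl2 (4.27 ± 0.90) rose as well. Derl3, an ER degradation factor, rose by 3.98 ± 0.93, and Sdf2l1, an ER chaperone partner, by 3.85 ± 1.03. The adjusted p of these genes ran from 0.00159 for Ptx3 to 0.0206 for Tk1. The largest falls were Fn3k, a kinase of sugar-modified proteins, by 4.74 ± 0.60, the mitochondrial carrier Slc25a34 by 4.19 ± 0.80, Ttll1 by 4.16 ± 0.73 and the myosin-binding protein Mybpc2 by 3.75 ± 0.72. Klf15, a transcription factor of cardiac metabolism, fell by 3.47 ± 0.40. Pdlim4 fell by 3.27 ± 0.77, Ccdc189 by 3.26 ± 0.78, the carboxylesterase Ces1d by 3.18 ± 0.50, Smco1 by 3.18 ± 0.52 and Tmem25 by 3.16 ± 0.87.

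Of 35 tested genes for ER chaperones and folding, 22 rose, and 26 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.7e-08, and adjusted p = 0.330 with an estimated correlation). They included the co-chaperones Dnajc3 (3.42 ± 0.53) and Creld2 (3.79 ± 0.71), the disulfide isomerase P4hb (3.25 ± 0.63) and the lectin chaperone Calr (2.24 ± 0.38). Of 28 genes of ER-associated degradation, 11 rose and 1 (Erlec1) fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.00409, and adjusted p = 0.396 with an estimated correlation). Edem1 rose by 1.51 ± 0.26, Edem3 by 1.38 ± 0.28, the segregase Vcp by 1.71 ± 0.32 and Selenos by 1.12 ± 0.20. For translocation into the ER and glycosylation, 12 of 36 rose and 1 (Srp68) fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 8.08e-06, and adjusted p = 0.311 with an estimated correlation). Examples were Spcs3 (1.22 ± 0.24) and Sec11c (1.20 ± 0.19) of the signal peptidase, Mogs (1.14 ± 0.21) and Gfpt1 (1.01 ± 0.19). Among 22 sensors and transcription factors of the unfolded protein response, 7 rose and 1, Atf6, fell, as also adjusted over the list alone (camera adjusted p = 0.00586, and adjusted p = 0.259 with an estimated correlation). The sensor kinase Eif2ak3 rose by 1.96 ± 0.28 and the transcription factor Ddit3, also called CHOP, by 2.08 ± 0.40. Yy1 rose by 0.73 ± 0.15, while another of its probe sets fell by 1.02 (adjusted p = 0.00871 over all probe sets tested). Of 25 targets of ATF4, 7 rose and 2 (Ddit4 and Vldlr) fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00044, and adjusted p = 0.311 with an estimated correlation), and 12 rose without the array labelled NTG tamoxifen 1, with Chac1 (2.85 ± 0.58) and Asns (2.41 ± 0.57) beside Mthfd2 and Psat1. Leaving out that array moved the estimated-correlation adjusted p past the threshold for all 5 lists, to 0.0226 for ER chaperones and folding, 0.0407 for the sensors and transcription factors and 0.0332 for the others.

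**Figure D3:**
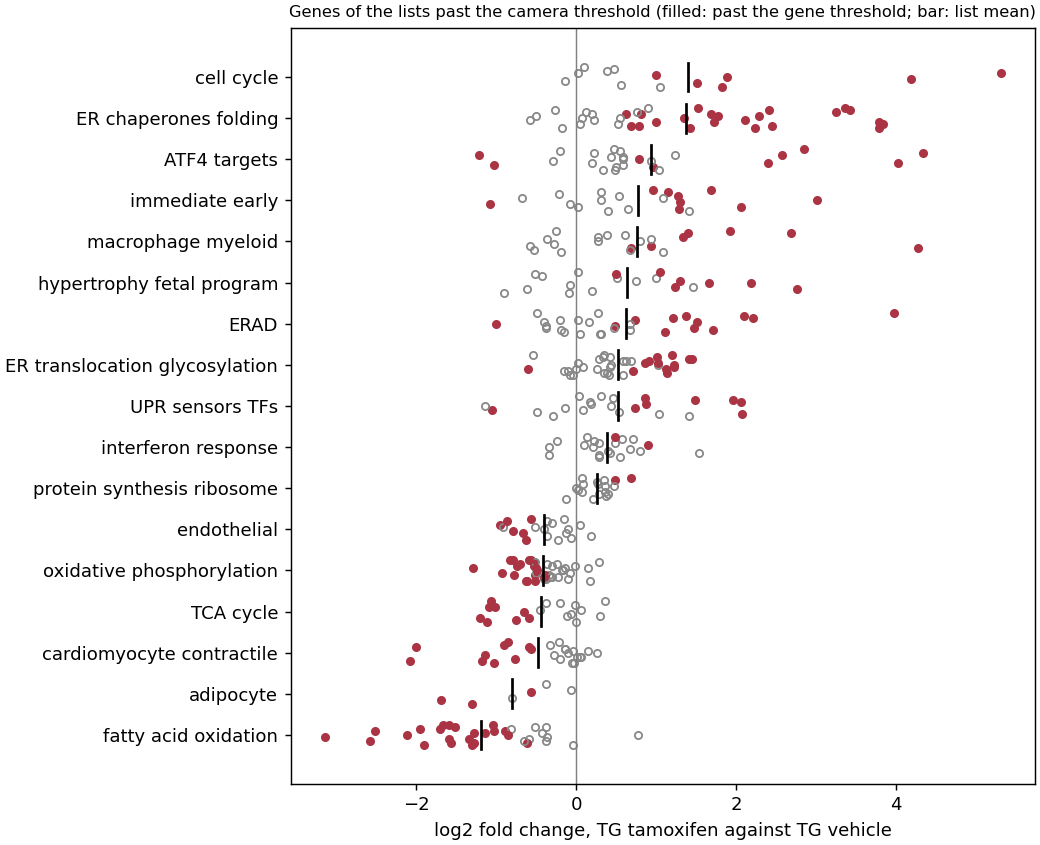
Log2 fold change in TG tamoxifen against TG vehicle of each tested gene of the 17 lists past the camera threshold, 1 point per gene, filled where the gene passed the limma threshold, with a bar at the list mean. Of the ER chaperones and folding list 22 of 35 genes rose, and of the fatty acid oxidation list 22 of 32 fell; with an estimated correlation these lists gave an adjusted p of 0.330 each, and 0.0226 and 0.0332 without the array labelled NTG tamoxifen 1.

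Fatty acid oxidation had 22 of 32 genes lower, 26 adjusted over the list alone (camera adjusted p = 2.03e-10, and adjusted p = 0.330 with an estimated correlation). Mlycd fell by 2.52 ± 0.33, Acaa2 by 1.91 ± 0.23, Hadha by 1.71 ± 0.24 and Acads by 1.59 ± 0.22. Of 39 genes of oxidative phosphorylation 19 fell, 22 adjusted over the list alone (camera adjusted p = 8.08e-06, and adjusted p = 0.311 with an estimated correlation). Ndufs3 fell by 1.29 ± 0.20, Atp5d by 0.83 ± 0.15, Uqcrc1 by 0.77 ± 0.16 and Ndufb8 by 0.74 ± 0.15. In the tricarboxylic acid cycle 8 of 18 fell, 9 adjusted over the list alone (camera adjusted p = 0.00893, and adjusted p = 0.396 with an estimated correlation), among them Ogdh (-1.11 ± 0.18), Dlat (-1.09 ± 0.19), Dlst (-1.07 ± 0.16) and Idh3g (-0.75 ± 0.17). Of 25 contractile genes of cardiomyocytes 10 fell, as also adjusted over the list alone (camera adjusted p = 0.00409, and adjusted p = 0.351 with an estimated correlation). The sarcomere genes Tcap (-2.08 ± 0.39), Ldb3 (-1.14 ± 0.20) and Mybpc3 (-1.03 ± 0.16) and the potassium channel partner Kcnip2 (-2.00 ± 0.21) were among them. Genes of hypertrophy and the fetal program had 7 of 19 higher, 8 adjusted over the list alone (camera adjusted p = 0.00409, and adjusted p = 0.311 with an estimated correlation), with Timp1 (2.76 ± 0.54), Fhl1 (2.19 ± 0.36), Ccn2 (1.30 ± 0.27) and Tgfb2 (1.05 ± 0.19). When the array labelled NTG tamoxifen 1 was left out, the estimated-correlation adjusted p was 0.0332 for fatty acid oxidation and 0.147 to 0.387 for the other lists of this paragraph.

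Markers of other cell types and states also moved. Of 21 macrophage and myeloid genes 7 rose, as also adjusted over the list alone (camera adjusted p = 0.00409, and adjusted p = 0.534 with an estimated correlation), among them the leukocyte marker Ptprc (1.40 ± 0.25), Ccr2 (2.69 ± 0.48) and Aif1 (1.34 ± 0.30). Of 13 cell cycle genes 6 rose, 7 adjusted over the list alone (camera adjusted p = 0.000502, and adjusted p = 0.259 with an estimated correlation), such as Top2a (1.82 ± 0.33), Mcm5 (1.51 ± 0.27) and Nusap1 (1.89 ± 0.45). Immediate early genes had 8 of 20 higher and 1 (Dusp1) lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.000377, and adjusted p = 0.259 with an estimated correlation), with Socs3 (3.02 ± 0.41), Egr1 (1.68 ± 0.27), Btg2 (1.28 ± 0.19) and Fosl2 (1.14 ± 0.22). Of 19 endothelial genes 6 fell, 7 adjusted over the list alone (camera adjusted p = 0.0139, and adjusted p = 0.396 with an estimated correlation), such as Ramp2 (-0.95 ± 0.26), Tie1 (-0.86 ± 0.19), Kdr (-0.79 ± 0.19) and Emcn (-0.56 ± 0.16). Of 6 adipocyte genes 3 fell, as also adjusted over the list alone: Slc36a2 (-1.69 ± 0.25), Cidea (-1.30 ± 0.27) and Scd1 (-0.56 ± 0.18) (camera adjusted p = 0.0220, and adjusted p = 0.311 with an estimated correlation). Of 21 interferon genes 2 rose, 1 adjusted over the list alone (camera adjusted p = 0.00908, and adjusted p = 0.396 with an estimated correlation): Ifit1 by 0.89 ± 0.22 and Psmb8 by 0.49 ± 0.16; without the array labelled NTG tamoxifen 1, 5 rose. Of 18 ribosomal and translation genes 2 rose, Rpl4 by 0.69 ± 0.20 and Rpl8 by 0.48 ± 0.15, with limma calling 0 adjusted over the list alone and 6 at an unadjusted p under 0.05 (camera adjusted p = 0.00409, and adjusted p = 0.351 with an estimated correlation). When the array labelled NTG tamoxifen 1 was left out, the estimated-correlation adjusted p was 0.0332 for the cell cycle and 0.128 to 0.517 for the other lists above. The other 17 tested lists did not pass, with camera adjusted p from 0.0591 for the proteasome to 0.948.

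NTG tamoxifen against NTG vehicle asked what the drug did without the transgene. The largest falls were Zfp979 by 4.10 ± 0.51 log2 units, the nuclear noncoding RNA Neat1 by 3.54 ± 0.56, Chml by 3.24 ± 0.65, the noncoding RNA Firre by 2.99 ± 0.51 and Acadsb, an enzyme of branched-chain amino acid breakdown, by 2.78 ± 0.45 (adjusted p from 0.0151 to 0.0250). The largest rises were the neuropeptide Npy by 2.07 ± 0.47, Rsph14 by 2.00 ± 0.49, Utf1 by 1.92 ± 0.41, Nanos1 by 1.88 ± 0.45 and Gpaa1 by 1.53 ± 0.34 (adjusted p from 0.0275 to 0.0442). Hspa5 read 0.32 ± 0.52 (adjusted p = 0.75), Rcan1 0.99 ± 0.45 (0.214), Atf6 -0.45 ± 0.21 (0.214) and Esr1 5.12 ± 1.49 (0.0749). Without the array labelled NTG tamoxifen 1 these read -0.50, 0.35, -0.20 and 2.68, and Esr1 then had an adjusted p of 0.0257. In all, 482 genes changed, 73 higher and 409 lower; the arrays did not overlap for 30.2% of all genes, where chance gives 10%. Median centring gave 47 higher and 924 lower of 971, and the count depended on single arrays: 828 without NTG tamoxifen 2, 23 without NTG tamoxifen 3, and 15, 0 and 3 without NTG vehicle 1, 2 and 3 (for the 0, limma gave 1869 at an unadjusted p under 0.05). The count was 419 without the array labelled NTG tamoxifen 1, of which 263 were among the 482. The 3' to 5' beta-actin ratio separated these groups without overlap (1.78 to 1.97 in NTG tamoxifen, 2.12 to 2.43 in NTG vehicle). It was not a term of the fit, so an effect of RNA quality cannot be told apart from the group here.

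The tricarboxylic acid cycle list had 4 of 18 genes lower in NTG tamoxifen, 11 adjusted over the list alone (camera adjusted p = 9.97e-06, and adjusted p = 0.664 with an estimated correlation), with Sucla2 (-1.5 ± 0.29) and Dld (-1.40 ± 0.28). Fatty acid oxidation had 3 of 32 lower, 9 adjusted over the list alone, with Acadm (-1.07 ± 0.21) and Hadhb (-1.01 ± 0.17), and oxidative phosphorylation 5 of 39, 7 adjusted over the list alone, with Ndufa5 (-1.18 ± 0.26) and Ndufs1 (-1.03 ± 0.23). Their camera adjusted p values were 0.0165 and 0.0282, and with an estimated correlation adjusted p = 0.748 and 0.664. Endothelial genes had 2 of 19 lower, 5 adjusted over the list alone (camera adjusted p = 0.0258, and adjusted p = 0.664 with an estimated correlation), Fabp4 by 1.13 ± 0.20 and Ets1 by 0.90 ± 0.17. ER chaperones and folding passed upward (camera adjusted p = 0.0165, and adjusted p = 0.748 with an estimated correlation), although its 1 gene past the threshold, Tmx3, fell by 0.90 ± 0.20; adjusted over the list alone 3 rose and 1 fell. ER-associated degradation (0.0258), ribosomal and translation genes (0.00574) and glucocorticoid response (0.0326) also passed upward by camera, with adjusted p = 0.664 each with an estimated correlation. Without the array labelled NTG tamoxifen 1, 3 of the 34 lists passed by camera: the tricarboxylic acid cycle (adjusted p = 0.000252), ribosomal and translation genes (0.0232) and glucocorticoid response (0.00831). With an estimated correlation each gave an adjusted p of 0.797. The other 5 calls ended, with camera adjusted p = 0.603 for ER chaperones and folding, 0.438 for ER-associated degradation, 0.748 for fatty acid oxidation, 0.438 for oxidative phosphorylation and 0.265 for endothelial genes. The mean log2 change of the fatty acid oxidation genes went from -0.32 to -0.0144. Of oxidative phosphorylation genes limma then called 0 (8 at an unadjusted p under 0.05). The group is then arrays 2 and 3, and NTG tamoxifen 2 read highest of the 12 arrays for the atrial genes Myl7 (15.12), Myl4 (14.94) and Sln (13.34), where the others reached 12.50, 13.40 and 10.79. The atrial list had a mean of 0.40 (camera adjusted p = 0.450), and 0.97 (0.223) without NTG tamoxifen 1. By camera 13 lists passed without NTG tamoxifen 2, 15 without NTG tamoxifen 3 and 5 without NTG vehicle 1, against 8 with all arrays. With an estimated correlation 0 passed in each of these, and the smallest adjusted p was 0.612, 0.584 and 0.715.

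The difference between the tamoxifen effects in TG and NTG was tested directly. The TG effect exceeded the NTG effect by 5.61 ± 0.79 log2 units for Neat1, 5.26 ± 1.27 for Ccl2, 4.98 ± 1.14 for the adhesion molecule Mcam, 4.74 ± 0.84 for the stress gene Gadd45g and 4.40 ± 0.89 for Ptx3 (adjusted p from 0.00643 to 0.0226). It lay below by -4.07 ± 1.08 for St8sia3, -4.0 ± 0.85 for Fn3k, -3.74 ± 1.02 for Mybpc2, -3.50 ± 0.63 for Exoc3l2 and -3.33 ± 0.66 for Npy (adjusted p from 0.0112 to 0.0339). For Hspa5 the difference was 2.09 ± 0.73 (adjusted p = 0.0747), and 2.91 without the array labelled NTG tamoxifen 1 (adjusted p = 0.000201, within 0.000201 to 0.490 over its alternatives). Its other probe sets gave 1.63 and 0.17 (adjusted p = 0.152 and 0.749 over all probe sets tested). For Rcan1 it was 0.89 ± 0.64 (adjusted p = 0.361), and 1.53 without that array (adjusted p = 0.0202). Atf6 gave -0.60 ± 0.29 (adjusted p = 0.181) and Esr1 -6.26 ± 2.10 (0.0658), or -0.86 (0.0162) and -3.82 (0.00252) without it. In all, 1593 genes differed, 838 higher and 755 lower, and with median centring 1518 higher and 335 lower of 1853. The count was 2546 without the array labelled NTG tamoxifen 1 and 864 without NTG tamoxifen 3. It was 730, 953 and 959 without TG tamoxifen 1, 2 and 3, 851 without TG vehicle 2, and 925, 639 and 828 without NTG vehicle 1, 2 and 3.

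Of 35 ER chaperone and folding genes 5 had the higher effect in TG, as also adjusted over the list alone (camera adjusted p = 0.00647, and adjusted p = 0.791 with an estimated correlation), among them Tmx3 (1.59 ± 0.29) and Ero1b (1.04 ± 0.28). Translocation and glycosylation had 7 of 36, 8 adjusted over the list alone (camera adjusted p = 0.0403, and adjusted p = 0.791 with an estimated correlation), with Srp9 (2.32 ± 0.48) and Gfpt1 (1.85 ± 0.27). Fatty acid oxidation had the lower effect in TG for 8 of 32, and 14 against 1 adjusted over the list alone (camera adjusted p = 0.000596, and adjusted p = 0.791 with an estimated correlation), with the lipid-sensing receptor Ppara (-2.24 ± 0.37) and Acaa2 (-1.64 ± 0.33). Cell cycle genes had 2 of 13 higher, Top2a (2.04 ± 0.46) and Mcm3 (1.37 ± 0.36), as also adjusted over the list alone (camera adjusted p = 0.00647, and adjusted p = 0.598 with an estimated correlation). Without the array labelled NTG tamoxifen 1 the counts were 22 for ER chaperones and folding, 13 with 1 lower for translocation, 22 for fatty acid oxidation and 5 for the cell cycle, and 11 of 34 lists passed by camera instead of 4. Their camera adjusted p values were then 1.85e-10, 0.00127, 1.78e-08 and 0.00127, and with an estimated correlation adjusted p = 0.0611 for the ER chaperones and 0.116 for the others, with 0 of the 34 lists past the threshold. Without NTG tamoxifen 2, 2 lists passed by camera, and with an estimated correlation 0 (smallest adjusted p = 0.934). Across the 11166 genes, which are not independent replicates, Pearson's r between the tamoxifen effects in TG and NTG was 0.0598, and -0.162 without the array labelled NTG tamoxifen 1.

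TG vehicle against NTG vehicle asked what the transgene did without the drug. Beside Esr1, the largest rises were Npy by 2.21 ± 0.47 log2 units, Tmem69 by 2.05 ± 0.34, the globin Hbb-b2 by 1.97 ± 0.44 and Cyp2c54 by 1.96 ± 0.28. Npy was also the largest rise in NTG tamoxifen against NTG vehicle (2.07). Both comparisons use the same NTG vehicle arrays, so its rises are not independent of each other. The largest falls were the transcription factor Maz by 2.61 ± 0.44, Ctif by 2.54 ± 0.45, Clasrp by 2.53 ± 0.35, Fbxo42 by 2.39 ± 0.55 and the kinase Dmpk by 2.27 ± 0.22. Hspa5 read -0.04 ± 0.52 (adjusted p = 0.975), Rcan1 0.84 ± 0.45 (0.289) and Atf6 -0.50 ± 0.21 (0.181). Rcan1's other probe set read 2.17 ± 0.58 (adjusted p = 0.0503 over all probe sets tested). Of 12 smooth muscle and pericyte genes 4 fell, 8 adjusted over the list alone (camera adjusted p = 1.61e-05, and adjusted p = 0.599 with an estimated correlation), with Smtn (-1.20 ± 0.28) and Notch3 (-0.97 ± 0.19). Of 19 clock genes 4 fell, or 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00239, and adjusted p = 0.599 with an estimated correlation), with Per1 (-1.46 ± 0.23) and Tef (-1.23 ± 0.25); without the array labelled NTG tamoxifen 1, 8 fell and 1 rose. In all, 405 genes changed, 155 higher and 250 lower; the arrays did not overlap for 30.8% of all genes, where chance gives 10%. Median centring gave 75 higher and 471 lower of 546, and without the array labelled NTG tamoxifen 1, which the comparison uses only for the spread, 813 changed. The count was 625 without TG vehicle 1 and 4 without TG vehicle 3, and 53, 2 and 12 without NTG vehicle 1, 2 and 3. The 3' to 5' beta-actin ratio separated these groups without overlap (1.32 to 1.68 in TG vehicle, 2.12 to 2.43 in NTG vehicle). It was not a term of the fit, so an effect of RNA quality cannot be told apart from the group here.

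TG tamoxifen against NTG tamoxifen compared the genotypes when both had the drug. Hspa5 was higher by 2.04 ± 0.52 log2 units (adjusted p = 0.00907), Rcan1 by 1.74 ± 0.45 (0.0107) and Esr1 by 4.06 ± 1.49 (0.0482), and Atf6 fell by 1.10 ± 0.21 (0.00201). They read 2.87, 2.38, 6.5 and -1.35 without the array labelled NTG tamoxifen 1. Hspa5's other probe sets read 2.08 and 0.30 (adjusted p = 0.00787 and 0.328 over all probe sets tested). With TG vehicle 3 regrouped Hspa5 missed the threshold (1.42, adjusted p = 0.143, within 1.11e-05 to 0.143 over its alternatives). Atf6's other probe sets read 0.17 and 0.04 (adjusted p = 0.659 and 0.911 over all probe sets tested), and the mean of its probe sets gave -0.29 (adjusted p = 0.230, within 0.000134 to 0.230 over its alternatives). Esr1 missed the threshold in 11 of 20 alternatives (adjusted p from 1.01e-05 to 0.204), among these without TG tamoxifen 1 (0.0918), 2 (0.0952) or 3 (0.106) and without NTG tamoxifen 2 (0.163) or 3 (0.192). The largest rises were Ccl2 (5.42 ± 0.90), Gadd45g (4.15 ± 0.59), Ptx3 (4.10 ± 0.63), Polr3k (4.05 ± 1.03) and Chml (4.0 ± 0.65). Of these, only Chml did not pass in TG tamoxifen against TG vehicle (1.04, adjusted p = 0.261). It fell in NTG tamoxifen against NTG vehicle (-3.24). The largest falls were Fn3k (-4.36 ± 0.60), Asb10 (-4.18 ± 0.50), Slc25a34 (-3.74 ± 0.80), Oplah (-3.56 ± 0.44) and Klf15 (-3.49 ± 0.40). Of 11166 genes 4409 changed, 2115 higher and 2294 lower, and 2555 higher and 1707 lower of 4262 with median centring. The arrays did not overlap for 51.0% of all genes, where chance gives 10%.

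Between TG tamoxifen and NTG tamoxifen 19 of 35 ER chaperone and folding genes were higher and 1 lower, or 20 and 1 adjusted over the list alone (camera adjusted p = 0.000447, and adjusted p = 0.655 with an estimated correlation), with Tmx3 (1.77 ± 0.20) and Hspa13 (1.23 ± 0.19). Translocation and glycosylation had 15 higher and 3 lower of 36, or 15 and 4 adjusted over the list alone (camera adjusted p = 0.00965), with Spcs3 (1.62 ± 0.24) and Gfpt1 (1.46 ± 0.19). Macrophage and myeloid genes had 11 of 21 higher, or 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000565), with Ptprc (2.02 ± 0.25) and Mrc1 (1.56 ± 0.20). Cell cycle genes had 5 of 13 higher, 7 adjusted over the list alone (camera adjusted p = 0.00965), with Pcna (1.58 ± 0.22) and Top2a (1.44 ± 0.33). Fatty acid oxidation had 2 higher and 20 lower of 32, or 5 and 20 adjusted over the list alone (camera adjusted p = 0.000565), with Ppara (-2.64 ± 0.26) and Ppargc1b (-1.75 ± 0.26). Contractile genes had 1 higher and 11 lower of 25, or 1 and 12 adjusted over the list alone (camera adjusted p = 0.0405), with Kcnip2 (-1.64 ± 0.21) and Mybpc3 (-1.37 ± 0.16). Smooth muscle and pericyte genes had 1 higher and 7 lower of 12, or 1 and 8 adjusted over the list alone (camera adjusted p = 0.0292), with Smtn (-1.90 ± 0.28) and Notch3 (-1.64 ± 0.19). Each of these lists gave an adjusted p = 0.655 with an estimated correlation. Without the array labelled NTG tamoxifen 1, 12 lists passed by camera instead of 7, and 8 cell cycle genes were higher. With an estimated correlation 0 lists passed in that fit, and the adjusted p of the 12 ran from 0.0548 for ER chaperones and folding to 0.451.

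TG tamoxifen against the mean of the other 3 groups set the TG group given the drug against all other groups. These hold the array labelled NTG tamoxifen 1, which read 17.72 for Esr1 and 18.05 for Hspa5, so they may not all be free of the active fusion. Hspa5 was higher by 2.27 ± 0.42 log2 units (adjusted p = 0.00167), Rcan1 by 2.11 ± 0.37 (0.00121) and Esr1 by 4.03 ± 1.21 (0.0198), and Atf6 fell by 1.23 ± 0.17 (0.000385). Atf6's other probe sets read 0.22 and 0.00545 (adjusted p = 0.480 and 0.985 over all probe sets tested), and the mean of its probe sets gave -0.34 (adjusted p = 0.0961, within 1.38e-05 to 0.0961 over its alternatives). Esr1 missed the threshold in 6 of 26 alternatives (adjusted p from 4.15e-06 to 0.202), among these without TG tamoxifen 1 (0.0574), 2 (0.0593) or 3 (0.0667). The largest rises were Far1 (5.08 ± 0.68), Polr3k (4.81 ± 0.84), Ptx3 (4.81 ± 0.51), Ccl2 (4.71 ± 0.73) and Ube2c (4.39 ± 1.0). The largest falls were Fn3k (-4.74 ± 0.49), Slc25a34 (-4.17 ± 0.65), Asb10 (-4.05 ± 0.41), Ttll1 (-3.71 ± 0.59) and Klf15 (-3.68 ± 0.33). In all, 4648 genes changed, 2092 higher and 2556 lower, and 2402 higher and 2184 lower of 4586 with median centring. Of the 34 lists 14 passed by camera, 10 upward and 4 downward, and with an estimated correlation the adjusted p of the ER chaperone and fatty acid oxidation lists was 0.408 each, or 0.0332 and 0.0519 without the array labelled NTG tamoxifen 1. Of the ER chaperone and folding genes 25 of 35 were higher, or 25 higher and 1 lower adjusted over the list alone, with Dnajc3 (3.04 ± 0.43) and Pdia6 (1.98 ± 0.29), and of fatty acid oxidation genes 24 of 32 were lower and 1 higher, or 25 and 1 adjusted over the list alone, with Ppara (-2.12 ± 0.22) and Acaa2 (-1.75 ± 0.19).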

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

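The tests of explanations in this part were chosen only after the results they bear on had been seen; the test of the difference between the tamoxifen effects in TG and NTG was planned.

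For 67 of 128 named genes the tamoxifen effect differed between TG and NTG in limma's test of the difference itself, with adjusted p from 0.00643 to 0.0490. Over all genes tested the share was 14.3%. The 128 were named mostly for passing in TG, in NTG or in this same test. Their share and the kinds of genes below are thus partly fixed by that choice. The values are the TG effect minus the NTG effect in log2 units. Among genes of ER folding, degradation, transport and signalling the TG effect was higher for Ddit3 (2.21), Eif2ak3 (2.00), Srp9 (2.32), Gfpt1 (1.85), Edem3 (1.80), Tmx3 (1.59), Vcp (1.5), Edem1 (1.22), Spcs3 (1.14), Sec11c (1.06), Selenos (1.05) and Ero1b (1.04). It was also higher for the proteasome genes Psmd14 (1.82), Psmc6 (1.76) and Psma5 (1.52), for the redox genes Txnrd1 (1.65) and Gclc (1.21) and for Mthfd2 (3.15). Of immune, cell cycle, matrix and early response genes, it was higher for Ccl2 (5.26), Ptx3 (4.40), Gadd45g (4.74), Ptprc (1.91), Ifit1 (2.26), Egr1 (2.09), Top2a (2.04), Mcm3 (1.37), Fn1 (1.51), Lox (1.15) and Fhl1 (2.21). The TG effect was lower for the fuel and mitochondrial genes Slc2a4 (-1.25), Pfkm (-1.83), Tpi1 (-1.32), Ldhb (-1.06), Mlycd (-2.03), Ppara (-2.24), Acaa2 (-1.64), Hadha (-1.26), Ogdh (-0.95), Ndufs3 (-1.14), Ndufb8 (-0.74) and Atp5d (-0.74). It was lower for the contractile and adipocyte genes Mybpc2 (-3.74), Kcnip2 (-1.28), Ldb3 (-0.97), Mybpc3 (-0.76), Cidea (-1.47) and Slc36a2 (-1.37), for Klf15 (-2.90), Smco1 (-3.29) and Fn3k (-4.0), for Gsta4 (-2.09) and Prdx2 (-0.75) and for the calcineurin subunit Ppp3cc (-1.69). For a further group the NTG effect passed the threshold: Neat1 (5.61), Zfp979 (4.37), Chml (4.28), Firre (3.73), Acadsb (2.73), Sucla2 (1.57), Fabp4 (1.06) and Ets1 (0.80) fell in NTG tamoxifen, and Npy (-3.33), Rsph14 (-2.47) and Gpaa1 (-1.67) rose there. The NTG effect also passed for Ifit1 (-1.37), Tmx3 (-0.90) and Gfpt1 (-0.84), and for Neat1 the TG effect passed too (2.07, adjusted p = 0.0210). For Mcam (4.98) and St8sia3 (-4.07) neither effect passed in its own group, and for Exoc3l2 (-3.50) the TG effect did. Every value uses the array labelled NTG tamoxifen 1.

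The array labelled NTG tamoxifen 1 read 17.72 log2 units for Esr1, within the TG range. That level was above every TG tamoxifen array (16.66 to 17.15) and below every TG vehicle array (17.89 to 18.25). A minor share of transgenic RNA in this sample was taken as Esr1 below 0.5 of the highest TG array on the linear scale. That highest array was TG vehicle 1. The array read 0.692, which goes against such a share for Esr1 alone. The bound was set after the Esr1 level had been seen and largely restates it, so it does not settle the share. A swap with another of the 12 arrays was argued against, since the lowest TG array exceeded the highest other NTG array by 5.78. Across genes, which are not independent replicates, the array's deviation from the rest of its group correlated with the TG tamoxifen effect at r = 0.509, against 0.0395 for the highest NTG vehicle array, and the difference between clock phases at -0.17 lay in the TG vehicle range (-1.51 to -0.01; -3.26 to -2.58 on the other NTG arrays). Ube2c, Far1, Polr3k, Hspa5 and Rcan1 lay above the other NTG arrays, with Ube2c at 14.71 in the TG tamoxifen range (14.05 to 14.72) and the others below it (16.67 against 17.89 to 18.07, 16.38 against 16.94 to 17.15, 18.05 against 18.37 to 18.47 and 15.17 against 15.29 to 15.95), whereas over the 338 genes lower in NTG tamoxifen when this array was left out it lay on the NTG tamoxifen side, at a mean of -0.88 against NTG vehicle, below every TG array (-0.39 to 0.16) and nearer to the other NTG tamoxifen arrays by which these genes were chosen (-1.11 and -1.43). A wrong label and a share of transgenic RNA of unknown size both stay open, and no biological explanation was tested.

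Zfp979, Neat1, Chml and Firre fell together in NTG tamoxifen against NTG vehicle, by a mean of 3.46 log2 units. More degraded RNA in NTG tamoxifen was argued against, since the 3' to 5' beta-actin ratio changed by -0.389 against NTG vehicle, away from degradation. The ratio still separated the groups without overlap (1.78 to 1.97 in NTG tamoxifen, 2.12 to 2.43 in NTG vehicle). Any other effect of RNA quality thus cannot be told apart from the group. Tamoxifen acting alike in both genotypes was argued against, since the same genes averaged 1.03 (SD over genes 0.76) in TG tamoxifen against TG vehicle. Their mean was 11.52 to 12.22 on TG tamoxifen arrays and 7.93 to 8.79 on NTG tamoxifen arrays. The SD is over genes, which are not independent replicates. These values show no fall in TG but not a rise: only Neat1 passed there (adjusted p = 0.0210), and TG vehicle 1 read 11.84, within the TG tamoxifen range. For a sample preparation that differed with the group, the bound set was a range over the TG vehicle arrays as large as the NTG change, and the range of 1.54 fell short of it. That bound was wrong by design, because such a preparation need not vary within a group and the labels give none, so preparation and group cannot be told apart.

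Clock genes differed in TG vehicle against NTG vehicle, where genes of the activator phase exceeded those of the output phase by 2.13, with the activator genes at a mean of 0.90 (SD over genes 0.82) and none of those 4 past limma's threshold. The phases were assigned after the values had been seen, so these values decide between no explanations. The same difference between phases was 3.56 in TG tamoxifen against NTG tamoxifen and 2.03 in TG tamoxifen against TG vehicle, within 1 genotype, where the arrays ran from 1.44 to 1.61 and from -1.51 to -0.01. Hearts taken at different times, a preparation difference and an action of the transgene therefore cannot be told apart, and the time of collection is not given in the sources used here.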

How the results depend on the processing

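The fits without the array labelled NTG tamoxifen 1 in comparisons that do not use it, without both arrays with conflicting labels, and with an estimated correlation while an array was left out, were chosen only after the results had been seen.

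Of the calls past the threshold, each of a named gene in 1 comparison, 404 of 405 were kept with an offset of 1, 410 of 411 with an offset of 64, 399 with the deposited scaling and 386 with median centring. With no filter 278 of 411 were kept, with the 75th percentile 316 of 316, with the mean of probe sets 303 of 378 (3 reversed), with the largest SD 305 of 349 (9 reversed), with only the arrays compared 275 of 349, with eBayes using trend and robust 408, with array weights 406, with TG vehicle 3 grouped as TG tamoxifen 143, and without both arrays with conflicting labels 230. Leaving out single arrays kept from 107 of 205 without NTG vehicle 2 to 284 of 294 without TG vehicle 1. The number of arrays, and for dim genes the signal over background, limit the precision.

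For TG tamoxifen against TG vehicle, no filter gave 1604 genes, the probe set with the largest SD 1694, and leaving out both arrays with conflicting labels 744; with TG vehicle 3 grouped as TG tamoxifen limma gave 0 (2280 at an unadjusted p under 0.05). Leaving out single arrays gave 1462 to 2817. For NTG tamoxifen against NTG vehicle, median centring gave 971, no filter 4, the mean of probe sets 202, the largest SD 294, trend and robust 759, array weights 748, only the arrays compared 21, TG vehicle 3 regrouped 98 and both arrays out 87, and single arrays 0 to 828. For TG vehicle against NTG vehicle, no filter gave 8, the 75th percentile 718, the mean of probe sets 151, trend and robust 648, array weights 1288, only the arrays compared 17, the array labelled NTG tamoxifen 1 left out 813 and both arrays out 5; regrouping gave 0 in limma (1395 at an unadjusted p under 0.05), and single arrays 2 to 625. For the difference between tamoxifen effects, no filter gave 361, the mean of probe sets 1045, the largest SD 913, array weights 2682 and both arrays out 65; regrouping gave 0 in limma (1988 at an unadjusted p under 0.05), and single arrays 639 to 2546. Single arrays gave 3392 to 4786 for TG tamoxifen against NTG tamoxifen and 3295 to 5114 against the mean of the other 3 groups. With no filter more genes are tested, and with the 75th percentile fewer. Leaving out arrays that a comparison does not use, or regrouping them among other unused groups, left its log2 changes as they were. Such settings acted only through the estimate of the spread. Otherwise the cause was not tested.

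Of the lists of TG tamoxifen against TG vehicle, 17 passed camera at the preset correlation, and 13 to 18 when single arrays were left out. With an estimated correlation 0 passed, also when each array of these groups was left out, but 7 passed without the array labelled NTG tamoxifen 1. Rcan1 in that comparison read 1.70 with TG vehicle 3 regrouped (adjusted p = 0.176) and 2.07 without both arrays (adjusted p = 0.0647), against 0.000698 to 0.176 over its alternatives; single arrays gave 1.68 to 2.08.

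Directions reversed with the mean of probe sets for Yy1 (-0.0878) and Psmb8 (-0.16) in TG tamoxifen against TG vehicle, Atf6 in NTG tamoxifen against NTG vehicle (0.10), and Atf6 (0.32), Hspa5 (0.18) and Dnajb5 (0.16) in TG vehicle against NTG vehicle. With the probe set of largest SD they reversed for Yy1 (-1.02) in TG tamoxifen against TG vehicle, for Lman1 (-0.68), Hadhb (0.40) and Ets1 (0.35) in NTG tamoxifen, for Hspa5 (0.46), Pfkfb3 (0.15) and Dnajb5 (1.33) in TG vehicle, for Txn1 (-1.13) and Igf1 (-0.34) in the difference between effects, and for Dnajb5 (0.0932) against the other 3 groups. Hspa5 in TG vehicle against NTG vehicle read 0.0587 with the deposited scaling and 0.00225 both with TG vehicle 3 regrouped and without both arrays, with -0.224 to 0.0911 over single arrays; in NTG tamoxifen it read -0.10 with array weights and -0.50 to 0.78 over single arrays. A different probe set explains the first 2 groups by construction; otherwise the cause was not tested.

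Nothing in the labels says that the replicate numbers pair the samples. Over 18 pairs of equal numbers the correlation of deviations ran from -0.09 to 0.09. With a replicate block limma gave 0 genes for NTG tamoxifen against NTG vehicle (2457 at an unadjusted p under 0.05), 0 for TG vehicle against NTG vehicle (2307) and 894 for the difference between effects, and 311 of 411 calls of named genes were kept.

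The 10 splits of 6 arrays are too few for a share under 0.05. Only 1 split, the real one, gave as many genes in each case: 2774 in TG tamoxifen against TG vehicle with 1 as the highest other, and 482, 405 and 4409 in the other comparisons of 2 groups with 0. A further 100 splits of the 12 arrays were the real one and random draws. Only the real one gave as many as the 1593 genes of the difference between effects (highest other 547). The same held for the 4648 genes against the mean of the other 3 groups (highest other 235). These draws mix all 4 groups, so they test whether the groups matter at all, and not the difference between effects or this contrast itself.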

Other observations

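The per-array reading of the atrial genes and the count of probe sets with no gene symbol or with several were chosen only after the results had been seen. The gene lists were planned.

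In TG tamoxifen against TG vehicle 7 of 28 proteasome genes rose, as also adjusted over the list alone (camera adjusted p = 0.0591). Of 25 antioxidant genes 8 rose and 6 fell, or 9 and 11 adjusted over the list alone, with a mean of 0.14 and a median of -0.34 (camera adjusted p = 0.948, upward). Of 18 glycolysis genes 5 rose and 7 fell, as also adjusted over the list alone (camera adjusted p = 0.509). Of 27 matrix genes 4 rose and 4 fell, or 7 and 6 adjusted over the list alone, with a mean of 0.09 and a median of -0.06 (camera adjusted p = 0.776, upward). Of 20 calcineurin signalling genes 2 rose and 4 fell, as also adjusted over the list alone, with a mean of 0.01, a median of -0.03 and a downward camera test (adjusted p = 0.948). Of 17 glucocorticoid response genes 3 rose and 7 fell, as also adjusted over the list alone (camera adjusted p = 0.494).

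The array labelled NTG tamoxifen 2 read highest of the 12 for the atrial genes Myl7 (15.12 log2 units), Myl4 (14.94) and Sln (13.34), where the others reached 12.50, 13.40 and 10.79.

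Of 3241 tested probe sets with no gene symbol or with several, 407 changed in TG tamoxifen against TG vehicle, 105 in NTG tamoxifen against NTG vehicle, 190 in TG vehicle against NTG vehicle, 1154 in TG tamoxifen against NTG tamoxifen, 288 in the difference between effects and 1006 against the mean of the other 3 groups.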
